A study of Mus musculus with 14 samples.

How the data were processed

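RNA of whole liver from 14 mouse samples was measured on Illumina mouse BeadChips, 1 array per sample. The mice had received, by hydrodynamic delivery, a plasmid for interleukin 13 (IL-13) or for the green fluorescent protein EGFP, and were killed 1 week later, per the labels' protocols. Hydrodynamic delivery is a rapid injection of a large volume into the tail vein that carries DNA into hepatocytes. Samples were grouped by the plasmid and genotype in their titles. The groups were wild type with EGFP (n = 4), Alb-Cre with EGFP (n = 4), wild type with IL-13 (n = 3) and Alb-Cre with IL-13 (n = 3). The series title places the Alb-Cre genotype on a floxed Il4ra background, in which the albumin promoter drives Cre recombinase in hepatocytes. Replicate numbers were read from the titles, and for the wild-type IL-13 samples the descriptions give other numbers. The labels do not state that each sample came from a separate mouse, so the p-values measure the spread between these samples.

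The deposited scanner tables hold a probe intensity on a linear scale and a detection p-value for each array, per the file headers. They were exported from GenomeStudio 2011.1, per the submitters' processing notes. The steps of the deposited detection p-value were compatible with a rank among 798 negative control beads. The authors also deposited a log2 table of the same arrays, and every column of it equalled the log2 of the intensity times 1 factor per array, between 4.52 and 4.85, that set the array's median to 500. What else was done before deposit is not given in the sources used here. The intensity tables were the starting point and the log2 table served as an alternative.

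In R 4.3.3, limma 3.58.1 estimated the background from the detection p-values, corrected it by normexp with an offset of 16, and applied quantile normalization and log2 (the neqc function). The array holds 25697 probes. The gene table of the platform gave 1 symbol to 23978 of them, several to 0 and none to 1719. Gene IDs of 23962 probes matched a RefSeq gene table of assembly GRCm38.p6, which changed 0 symbols and was used for names only. A probe was kept when its detection p was under 0.05 on at least 3 arrays, which left 14109 probes. Of these, 13274 carried a symbol and represented 9711 genes, and 835 did not and were left out of the gene counts. 2570 genes had more than 1 kept probe, and the probe with the highest mean over all arrays stood for the gene. No probe carried the symbol Il4ra, so the floxed gene is not analysed here. The same holds for Epcam and Spp1. Probes for Krt19, Mmp12 and Epx did not pass the filter. Probes of near-identical families, such as the Mup, Cyp2b and Cyp4a genes, can bind each other's transcripts.

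A limma model with 1 mean per group and 1 spread per gene over all 14 arrays (10 residual degrees of freedom) gave 5 contrasts: IL-13 against EGFP within each genotype, the difference of these responses (Alb-Cre minus wild type), and Alb-Cre against wild type under each plasmid. Tests were two-sided, with Benjamini-Hochberg adjustment over 9711 genes and a threshold of 0.05. Log2 changes are given with limma's standard error after the ± sign, and group means with their SD. A gene not detected on any array of a group (detection p of 0.05 or more) has only a bound there. Its fold is written as "at least", from the bright group's mean against the dim group's mean of, per array, the higher of the lowest detected signal and the probe's own. The fit was tested on simulated data with known changes in 9711 genes. It recovered 95.5% of changes of 1 log2 unit in the wild-type comparison, 94.0% in Alb-Cre, 76.1% in the difference of responses and 89.5% between genotypes under IL-13. For changes of 0.5 these shares were 51.5%, 34.3%, 8.96% and 38.8%. The simulation gave 130 calls for the difference of responses, where the real data gave 1277. The adjusted threshold was therefore stricter in the simulation, and the shares are not estimates for the real data.

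The 36 gene lists for liver pathways and for the cell types a whole liver can hold were fixed before the data were examined, as were the model, the filter, the rule for named genes and most alternatives. Lists with at least 5 measured members were tested with limma's camera at a preset correlation between genes of 0.01. Camera with the correlation estimated per list, and fry, were alternatives. Eosinophil markers (2 measured) and adipocyte genes (4 measured) were described without a set test. The rule named the 8 largest rises and falls of each IL-13 contrast whose arrays did not overlap, the 8 largest differences of responses in each direction, and the 5 largest genotype differences in each direction. It passed over clone and predicted names. It added up to 4 members per list with the smallest p, and a fixed set of IL-13, matrix, bile acid, lipid and cell type genes. Eif2s3y and Kdm5d were named after their values were seen.

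Replicates of a group correlated with r between 0.980 and 0.993 across probes, and no 2 arrays held identical values. The arrays lay on 2 slides, the first with 2 arrays of each group and the second with 2 EGFP arrays and 1 IL-13 array of each genotype. Values on slide 2 therefore rest on 1 IL-13 array per genotype, assumed to vary like the EGFP arrays. Counts and list medians are therefore also given with the slide as a block and within each slide. Other alternatives changed the normalization, the offset, the filter, the unit counted (probes), the samples in the fit, array weights, the empirical Bayes settings and the thresholds, used the replicate number as a block, and left out each array in turn. After seeing that Eif2s3y and Xist did not have the same pattern on all arrays, 3 alternatives were added: a covariate for whether Eif2s3y exceeded Xist, a fit with only the IL-13 arrays where it did, and a fit without the sex-biased lists.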

Results

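Liver expression profiles were collected from wild-type and Alb-Cre mice 1 week after delivery of an IL-13 or an EGFP plasmid. IL-13 is a type 2 cytokine that signals through a receptor containing the IL-4 receptor alpha chain, the product of Il4ra. Per the series title, Cre acts in hepatocytes on a floxed Il4ra. The design therefore asks how loss of Il4ra in hepatocytes changes the liver's response to IL-13, although these arrays do not measure that loss. The 14 arrays were of similar depth. Between 11554 and 13261 of 25697 probes were detected per array (45.0 to 51.6%), and the mean intensity lay between 283 and 354. The first principal component held 63.1% of the variance and separated the 6 IL-13 arrays from the 8 EGFP arrays. The number of arrays (4, 4, 3 and 3) limits the precision of every value.

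The delivered gene was read by a single probe, detected on all 14 arrays near the floor. Il13 measured 4.76 ± 0.15 (SD, n = 4) with EGFP and 4.62 ± 0.16 (SD, n = 3) with IL-13 in wild type, a change of -0.13 ± 0.15, adjusted p = 0.537. In Alb-Cre the change was -0.24 ± 0.15, adjusted p = 0.307. The labels do not say which Il13 sequence the plasmid carries or whether this probe reads it.

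Sex-linked transcripts divided the arrays. Xist, the RNA of the inactive X chromosome, was detected on 10 arrays, namely all 8 EGFP arrays and wild-type IL-13 replicates 1 and 2. The Y-linked genes Eif2s3y and Kdm5d were detected on the other 4, wild-type IL-13 replicate 3 and the 3 Alb-Cre IL-13 arrays, where Xist was not. In Alb-Cre this pattern therefore coincided with the plasmid on every array. The alternatives treat it as the animals' sex, and an exchange of samples was not tested as its source. Retnla was undetected on the 8 EGFP arrays and detected on the 6 IL-13 arrays, whichever sex-linked transcripts they had. Values that allow for it are given beside the gene groups it moves with.

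**Figure D1:**
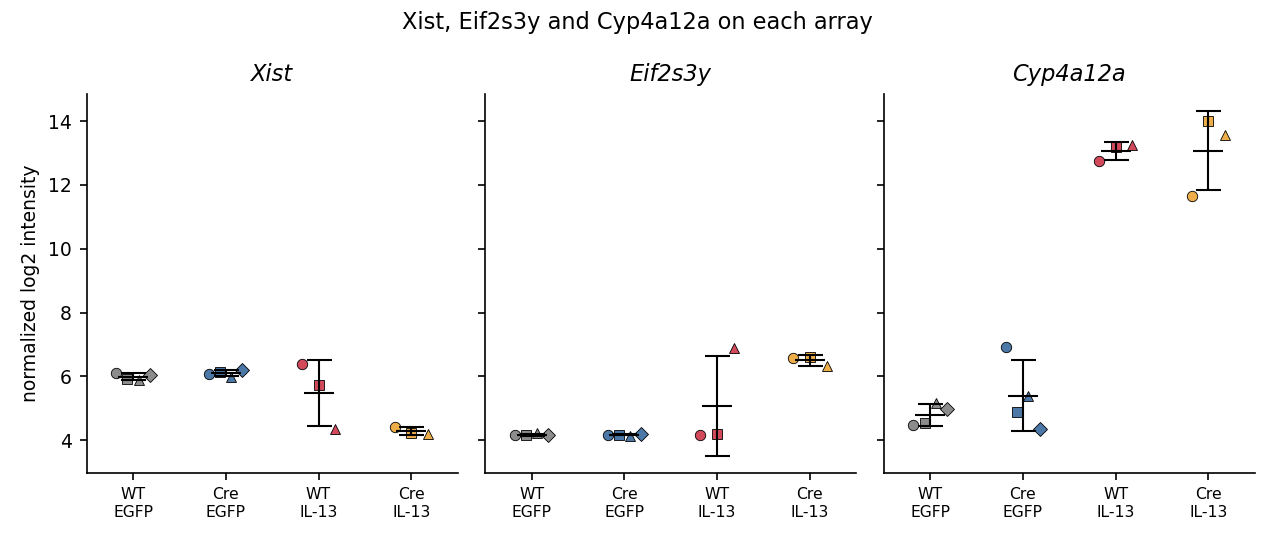
Normalized log2 intensity of Xist, Eif2s3y and the male-biased gene Cyp4a12a on each array, by group, with the group mean (long bar) and SD (short bars). Xist and Eif2s3y exclude each other on all 14 arrays, whereas Cyp4a12a is high on all 6 IL-13 arrays.

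In wild-type liver, IL-13 raised alternatively activated macrophage genes and collagens and lowered the enzymes that make bile acids, sterols and fatty acids and that metabolize drugs. Of these lists, bile acid and cholesterol synthesis did not pass the set test with an estimated correlation. Retnla, a secreted product of alternatively activated macrophages, rose at least 198-fold, from 4.28 ± 0.028 (SD, n = 4) to 12.15 ± 0.31 (SD, n = 3, adjusted p = 5.32e-14). Chil3, a chitinase-like protein of the same cells, rose at least 168-fold (adjusted p = 1.58e-11). Col6a2, a collagen VI chain, rose by 6.62 ± 0.16 on the log2 scale (adjusted p = 2.00e-13). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had a log2 change of -6.92 ± 0.46 (adjusted p = 1.19e-08), and Thrsp, a regulator of lipogenesis, one of -7.43 ± 0.30 (adjusted p = 3.25e-11). Of 9711 genes, 3952 changed. They comprised 2090 rises and 1862 falls, of which 588 and 487 were at least 2-fold. Genes said below to have risen, fallen or differed had an adjusted p under 0.05, and brackets give log2 changes.

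Type 2 immune genes rose, as 17 of 19 rose and 0 fell (17 and 0 adjusted over the list alone). They included the eosinophil chemokines Ccl11 (5.44 ± 0.21) and Ccl24 (1.75 ± 0.25), the macrophage lectin Mgl2 (2.76 ± 0.11) and the cytokine-induced suppressor Cish (3.41 ± 0.23). Rnase2a, of the eosinophil-associated ribonuclease family, rose at least 146-fold (adjusted p = 1.48e-12), the decoy receptor Il13ra2 at least 3.16-fold (adjusted p = 1.57e-08) and the cholesterol hydroxylase Ch25h at least 5.09-fold (adjusted p = 1.58e-11). Arg1, which hepatocytes also express, rose by 0.45 ± 0.13. The type 2 median was 2.01 (1.96 with the slide as a block, 2.43 on slide 1, 2.29 on slide 2), with camera adjusted p = 1.49e-13 and adjusted p = 0.0143 with an estimated correlation. With the 8 members undetected in a group held at their bound it was 1.75.

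Matrix genes rose, as 25 of 32 rose and 1 fell (26 and 1 adjusted over the list alone). Among them were the collagen genes Col1a1 (3.98 ± 0.27) and Col3a1 (3.22 ± 0.23) and the proteoglycan Lum (4.34 ± 0.21), and the collagen cross-linking enzyme Lox rose at least 13.05-fold (adjusted p = 1.58e-11). The matrix median was 1.92 (1.90 with the slide as a block, 1.93 on slide 1, 1.58 on slide 2), with camera adjusted p = 3.40e-14 and adjusted p = 0.0361 with an estimated correlation. Of stellate cell and myofibroblast markers 9 of 17 rose and 4 fell (9 and 4 adjusted over the list alone), with opposite changes of Cygb (3.15 ± 0.24) and Reln (-2.94 ± 0.18). The smooth muscle actin gene Acta2 rose on its brightest probe (2.21 ± 0.39), and 2 of its 4 probes passed. The stellate median was 0.39 (0.38 with the slide as a block, 0.48 on slide 1, 0.31 on slide 2), with camera adjusted p = 0.00970 and adjusted p = 0.0983 with an estimated correlation. With its 2 members undetected in a group held at their bound it was 0.25.

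Lipid and sterol synthesis genes fell, although the set test of the sterol list did not pass with an estimated correlation. Of cholesterol synthesis genes 16 of 18 fell and 0 rose (16 and 0 adjusted over the list alone), including Dhcr7 (-2.84 ± 0.28), Tm7sf2 (-2.44 ± 0.22) and Hmgcs1 (-1.68 ± 0.37). The brightest Sqle probe did not pass (-1.30 ± 0.60, adjusted p = 0.102), and the other fell. The cholesterol median was -1.69 (-1.67 with the slide as a block, -1.88 on slide 1, -1.48 on slide 2), with camera adjusted p = 2.04e-08 and adjusted p = 0.205 with an estimated correlation. Of fatty acid and triglyceride synthesis genes 18 of 22 fell and 0 rose (18 and 0 adjusted over the list alone). They included the desaturase Scd1 (-6.07 ± 0.55), the elongase Elovl6 (-3.90 ± 0.34) and the lipogenic transcription factor genes Srebf1 (-3.499 ± 0.20) and Mlxipl (-2.27 ± 0.17), and Fasn fell at least 1.71-fold (adjusted p = 0.00334). The fatty acid synthesis median was -1.36 (-1.32 with the slide as a block, -1.26 on slide 1, -1.48 on slide 2), with camera adjusted p = 2.22e-10 and adjusted p = 0.0229 with an estimated correlation.

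Bile acid and drug metabolism genes fell, although of these lists drug metabolism alone passed the set test with an estimated correlation. Of bile acid synthesis genes 8 of 15 fell and 2 rose (8 and 2 adjusted over the list alone), among them Cyp8b1, which sets the share of cholic acid (-6.77 ± 0.43). The bile acid synthesis median was -0.50 (-0.41 with the slide as a block, -0.55 on slide 1, -0.25 on slide 2), with camera adjusted p = 0.00586 and adjusted p = 0.147 with an estimated correlation. Of bile acid and sterol transporters and regulators 10 of 20 fell and 3 rose (11 and 3 adjusted over the list alone). Abcb11, the bile salt export pump (-2.99 ± 0.30), and the sterol exporter Abcg8 (-1.97 ± 0.29) fell, and the flippase Atp8b1 rose (1.72 ± 0.23). The transporter median was -0.54 (-0.57 with the slide as a block, -0.41 on slide 1, -0.63 on slide 2), with camera adjusted p = 0.0152 and adjusted p = 0.110 with an estimated correlation. Of drug metabolism genes 29 of 39 fell and 3 rose (30 and 4 adjusted over the list alone), with falls of the cytochrome P450 genes Cyp3a11 (-6.59 ± 0.38), Cyp1a2 (-5.98 ± 0.20) and Cyp2b13 (-8.04 ± 0.30). Of 2 Cyp2c29 probes, 1 fell. The drug metabolism median was -1.15 (-1.14 with the slide as a block, -1.17 on slide 1, -1.22 on slide 2), with camera adjusted p = 9.35e-11 and adjusted p = 0.0166 with an estimated correlation.

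Other hepatocyte genes changed as well. Car3, a carbonic anhydrase abundant in hepatocytes, fell at least 209-fold (adjusted p = 2.56e-10), and the hepcidin gene Hamp2 (-7.35 ± 0.53) and the uridine phosphorylase Upp2 (-6.07 ± 0.34) fell too. Of hepatocyte markers 12 of 25 fell and 0 rose (12 and 0 adjusted over the list alone), among them Alb (-1.56 ± 0.20). The hepatocyte median was -0.54 (-0.51 with the slide as a block, -0.45 on slide 1, -0.27 on slide 2), with camera adjusted p = 8.20e-04 and adjusted p = 0.0983 with an estimated correlation. In contrast, of fatty acid oxidation and PPAR alpha genes 17 of 30 rose and 3 fell (17 and 3 adjusted over the list alone). The fatty acid hydroxylase Cyp4a14 (5.47 ± 0.69) and the pyruvate dehydrogenase kinase Pdk4 (3.07 ± 0.35) rose, as did the hormone gene Fgf21 (3.503 ± 0.34), while Ppara itself fell (-1.41 ± 0.17). The oxidation median was 0.42 (0.43 with the slide as a block, 0.34 on slide 1, 0.32 on slide 2), with camera adjusted p = 0.01005 and adjusted p = 0.352 with an estimated correlation. Of lipid droplet and uptake genes 9 of 19 rose and 3 fell (9 and 3 adjusted over the list alone), with rises of the droplet proteins Cidec (3.81 ± 0.25) and Plin2 (1.25 ± 0.24) and of the apolipoprotein Apoa4 (3.16 ± 0.18). Pparg rose on 1 of 2 probes and the fatty acid transporter Cd36 by 0.41 ± 0.12. The lipid droplet median was 0.35 (0.31 with the slide as a block, 0.25 on slide 1, 0.33 on slide 2), with camera adjusted p = 0.0248 and adjusted p = 0.205 with an estimated correlation.

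Markers of several immune cells rose, although none of these lists passed the set test with an estimated correlation. Of neutrophil markers 9 of 11 rose and 0 fell (10 and 0 adjusted over the list alone), including the calgranulin S100a8 (3.25 ± 0.49). The neutrophil median was 1.52 (1.502 with the slide as a block, 1.26 on slide 1, 0.87 on slide 2), with camera adjusted p = 2.35e-04 and adjusted p = 0.196 with an estimated correlation. Of monocyte and infiltrating macrophage markers 13 of 19 rose and 3 fell (13 and 3 adjusted over the list alone), with rises of the chemokine Ccl6 (3.82 ± 0.16) and the galectin Lgals3 (3.10 ± 0.14). The monocyte median was 0.81 (0.85 with the slide as a block, 0.83 on slide 1, 0.92 on slide 2), with camera adjusted p = 2.32e-04 and adjusted p = 0.147 with an estimated correlation. Of Kupffer cell markers 8 of 13 rose and 2 fell (8 and 2 adjusted over the list alone), with a rise of the complement gene C1qc (1.73 ± 0.12) and a fall of the lectin Clec4f (-2.22 ± 0.25). The Kupffer cell median was 0.61 (0.61 with the slide as a block, 0.43 on slide 1, 0.84 on slide 2), with camera adjusted p = 0.0240 and adjusted p = 0.352 with an estimated correlation. Of interferon stimulated genes 19 of 28 fell and 2 rose (20 and 2 adjusted over the list alone), including the antiviral gene Oas2 (-1.77 ± 0.15) and the GTPase Gbp3 (-3.04 ± 0.23), and 2 of 3 Ifit3 probes fell. The interferon median was -0.71 (-0.70 with the slide as a block, -0.81 on slide 1, -0.65 on slide 2), with camera adjusted p = 4.09e-07 and adjusted p = 0.0644 with an estimated correlation.

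Stress and injury genes rose, although of these lists injury alone passed the set test with an estimated correlation. Of genes of the damaged or fetal hepatocyte 12 of 17 rose and 0 fell (12 and 0 adjusted over the list alone), and Ly6d rose at least 194-fold (adjusted p = 2.46e-07) and the tetraspanin Cd63 by 3.32 ± 0.17. The injury median was 1.36 (1.33 with the slide as a block, 1.38 on slide 1, 1.63 on slide 2), with camera adjusted p = 2.45e-05 and adjusted p = 0.0166 with an estimated correlation. Of acute phase genes 17 of 28 rose and 1 fell (18 and 1 adjusted over the list alone), among them the endotoxin co-receptor Cd14 (6.06 ± 0.26) and the endotoxin-binding protein Lbp (2.01 ± 0.28). The acute phase median was 1.00 (0.96 with the slide as a block, 0.50 on slide 1, 1.29 on slide 2), with camera adjusted p = 2.54e-04 and adjusted p = 0.373 with an estimated correlation. Of unfolded protein response genes 15 of 21 rose and 1 fell (15 and 2 adjusted over the list alone). The brightest Asns probe rose at least 26.9-fold (adjusted p = 2.05e-08), and Chac1 rose by 4.64 ± 0.56. All 3 Asns probes rose, by 0.41 to 5.01. The unfolded protein response median was 0.69 (0.71 with the slide as a block, 0.64 on slide 1, 0.88 on slide 2), with camera adjusted p = 2.37e-04 and adjusted p = 0.123 with an estimated correlation. The ductular marker Sox9 rose (1.45 ± 0.17), whereas Krt7 did not pass (0.071 ± 0.13, adjusted p = 0.702) and Cd24a was undetected on the EGFP arrays.

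All 3 IL-13 arrays lay above, or all below, the 4 EGFP arrays for 3637 of the 3952 genes and for 106 of the 108 named genes that changed. They did so for 43.5% of all genes tested, where chance gives 5.71%. The count was 4027 with the slide as a block and 2669 on slide 1. The 108 named genes kept their sign on both slides, which for the 106 without overlap is fixed in advance. Without replicate 3, the wild-type IL-13 array with Eif2s3y, 3738 genes changed.

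**Figure D2:**
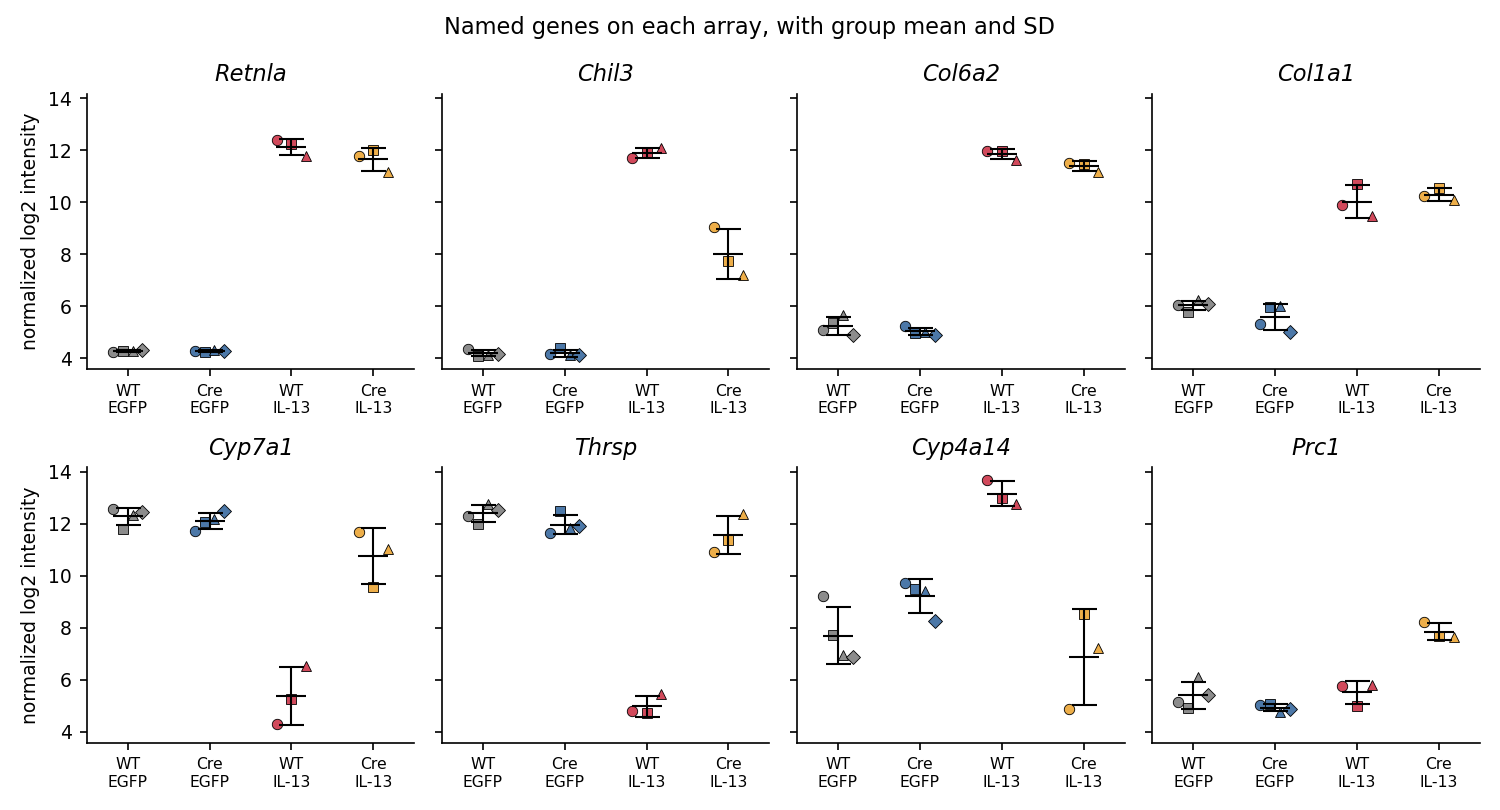
Normalized log2 intensity of 8 named genes on each array (a symbol per replicate number), by group, with the group mean (long bar) and SD (short bars). Retnla and the collagens are high on all 6 IL-13 arrays, whereas Cyp7a1, Thrsp and Cyp4a14 separate the IL-13 arrays of the 2 genotypes.

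In Alb-Cre liver, collagens, macrophage genes, cell cycle genes and male-biased liver genes were higher with IL-13 than with EGFP, and genes of fatty acid oxidation lower. With the sex pattern as a covariate, which also lowers precision, fewer of them passed. There were 7 instead of 18 rises for cell cycle, 4 instead of 12 for male-biased and 1 instead of 20 falls for oxidation genes. Retnla rose at least 137-fold, from 4.28 ± 0.031 (SD, n = 4) to 11.65 ± 0.44 (SD, n = 3, adjusted p = 1.43e-13). Col6a2 rose by 6.36 ± 0.16 (adjusted p = 4.14e-13), Col1a1 by 4.72 ± 0.27 (adjusted p = 5.49e-09) and the mitotic spindle gene Prc1 by 2.93 ± 0.25 (adjusted p = 5.08e-07). Cyp7a1 did not pass (-1.37 ± 0.46, adjusted p = 0.0503), nor did Thrsp (-0.40 ± 0.30, adjusted p = 0.396). With the sex pattern as a covariate Cyp7a1 fell (-3.12, adjusted p = 0.0141) and Thrsp did not pass (-1.10, adjusted p = 0.242). Of 9711 genes 1840 changed. They comprised 1080 rises and 760 falls, of which 357 and 119 were at least 2-fold. Every Alb-Cre IL-13 array had Eif2s3y and no Xist, and every Alb-Cre EGFP array the reverse. With this sex pattern as a covariate, a term estimated from the wild-type IL-13 arrays alone, 815 genes passed, 590 of them among the 1840. The term sets replicate 3 against replicates 1 and 2. Replicate 3 alone lay on slide 2 and had Reg3b at 10.07, so sex, slide and this array cannot be told apart. It makes the Alb-Cre change less precise, so a lost call need not mean a sex effect. Medians without and with it were 0.71 and 0.54 for cell cycle, 2.31 and 0.94 for male-biased and -0.70 and -0.36 for oxidation genes.

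Of matrix genes 27 of 32 rose and 0 fell (30 and 0 adjusted over the list alone), and 23 rose and 0 fell with the sex pattern as a covariate. Col3a1 (3.88 ± 0.23), Lum (2.80 ± 0.21) and Col14a1 (1.98 ± 0.20) were among them, Lox rose at least 11.1-fold (adjusted p = 7.25e-11), and the collagenase Mmp13 rose on 1 of 2 probes. The matrix median was 2.13 (2.12 with the slide as a block, 2.12 on slide 1, 2.09 on slide 2), with camera adjusted p = 2.54e-33 and adjusted p = 0.00754 with an estimated correlation. Of stellate cell and myofibroblast markers 11 of 17 rose and 2 fell (11 and 2 adjusted over the list alone), and 8 rose and 0 fell with the sex pattern as a covariate. Acta2 rose on all 4 probes, by 2.91 ± 0.39 on the brightest. The stellate median was 0.85 (0.86 with the slide as a block, 0.83 on slide 1, 0.59 on slide 2), with camera adjusted p = 9.45e-07 and adjusted p = 0.00754 with an estimated correlation. Of type 2 genes 13 of 19 rose and 0 fell (13 and 0 adjusted over the list alone), and 9 rose and 0 fell with the sex pattern as a covariate. Ccl11 rose by 2.87 ± 0.21 and Cish by 3.54 ± 0.23, Chil3 at least 10.9-fold (adjusted p = 1.28e-07) and Il13ra2 at least 3.53-fold (adjusted p = 1.10e-08). The type 2 median was 0.76 (0.76 with the slide as a block, 0.89 on slide 1, 0.56 on slide 2), with camera adjusted p = 3.28e-13 and adjusted p = 0.00754 with an estimated correlation. With members undetected in a group held at their bound it was 0.73.

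Few lipid synthesis genes passed. Of cholesterol synthesis genes 1 of 18 rose and 0 fell (0 and 0 adjusted over the list alone), and 0 rose and 0 fell with the sex pattern as a covariate. The cholesterol median was 0.14 (0.15 with the slide as a block, 0.22 on slide 1, 0.20 on slide 2), with camera adjusted p = 0.509. Of fatty acid synthesis genes 1 of 22 rose and 4 fell (1 and 5 adjusted over the list alone), and 0 rose and 0 fell with the sex pattern as a covariate. The fatty acid synthesis median was -0.32 (-0.31 with the slide as a block, -0.48 on slide 1, 0.23 on slide 2), with camera adjusted p = 0.0490 and adjusted p = 0.366 with an estimated correlation. Scd1 was not called (-0.021 ± 0.55, adjusted p = 0.987), but passed at 1.01 on slide 2 and at 1.07 without IL-13 replicate 2. Of drug metabolism genes 13 of 39 fell and 1 rose (20 and 4 adjusted over the list alone), and 1 rose and 5 fell with the sex pattern as a covariate. The female-biased Cyp2b13 fell at least 183-fold (adjusted p = 5.77e-11) and Cyp2b9 at least 217-fold (adjusted p = 3.63e-08), which passed with the sex pattern as a covariate at a smaller -4.76. The drug metabolism median was -0.42 (-0.40 with the slide as a block, -0.58 on slide 1, -0.26 on slide 2), with camera adjusted p = 8.97e-07 and adjusted p = 0.0282 with an estimated correlation. Of fatty acid oxidation and PPAR alpha genes 20 of 30 fell and 0 rose (23 and 0 adjusted over the list alone), and 0 rose and 1 fell with the sex pattern as a covariate. The thioesterase Acot1 (-1.98 ± 0.29) and the hydroxylase Cyp4a31 (-2.29 ± 0.34) were among those that fell. The oxidation median was -0.70 (-0.69 with the slide as a block, -0.71 on slide 1, -0.50 on slide 2), with camera adjusted p = 2.46e-11 and adjusted p = 0.0282 with an estimated correlation.

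Of cell cycle genes 18 of 29 rose and 1 fell (21 and 2 adjusted over the list alone), and 7 rose and 0 fell with the sex pattern as a covariate. The survivin gene Birc5 rose by 1.22 ± 0.14 and the topoisomerase Top2a at least 2.62-fold (adjusted p = 7.93e-07), while the thymidine kinase Tk1 fell (-1.18 ± 0.26). The cell cycle median was 0.71 (0.72 with the slide as a block, 0.72 on slide 1, 0.58 on slide 2), with camera adjusted p = 1.74e-09 and adjusted p = 0.0282 with an estimated correlation. Of antigen presentation genes 8 of 12 rose and 0 fell (8 and 0 adjusted over the list alone), and 5 rose and 0 fell with the sex pattern as a covariate, including Cd74 (2.18 ± 0.14) and H2-Ab1 (1.86 ± 0.16). The antigen presentation median was 0.62 (0.63 with the slide as a block, 0.52 on slide 1, 0.81 on slide 2), with camera adjusted p = 8.27e-08 and adjusted p = 0.0369 with an estimated correlation. Of neutrophil markers 8 of 11 rose and 0 fell (8 and 0 adjusted over the list alone), and 7 rose and 0 fell with the sex pattern as a covariate, S100a8 rising by 3.15 ± 0.49. The neutrophil median was 1.15 (1.12 with the slide as a block, 1.28 on slide 1, 0.92 on slide 2), with camera adjusted p = 1.03e-05 and adjusted p = 0.135 with an estimated correlation. Of monocyte markers 12 of 19 rose and 0 fell (12 and 0 adjusted over the list alone), and 6 rose and 0 fell with the sex pattern as a covariate. The monocyte median was 0.78 (0.78 with the slide as a block, 0.84 on slide 1, 0.48 on slide 2), with camera adjusted p = 2.57e-07 and adjusted p = 0.0486 with an estimated correlation. Of red cell genes 4 of 8 rose and 0 fell (6 and 0 adjusted over the list alone), and 0 rose and 0 fell with the sex pattern as a covariate, including the anion exchanger Slc4a1 (3.74 ± 0.64). The red cell median was 1.13 (1.15 with the slide as a block, 1.07 on slide 1, 0.79 on slide 2), with camera adjusted p = 6.60e-04 and adjusted p = 0.209 with an estimated correlation. Of acute phase genes 8 of 28 rose and 1 fell (13 and 1 adjusted over the list alone), and 0 rose and 1 fell with the sex pattern as a covariate. The acute phase median was 0.52 (0.51 with the slide as a block, 0.72 on slide 1, 0.26 on slide 2), with camera adjusted p = 2.17e-04 and adjusted p = 0.373 with an estimated correlation.

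Sex-biased liver genes changed in Alb-Cre, where plasmid and sex pattern coincide. The male-biased list holds Y-linked genes such as Eif2s3y and Kdm5d, and the female-biased list holds Xist. Part of the counts, medians and set tests of these lists therefore follows from the sex pattern itself. Apart from Xist and Y-linked genes, 17 genes of the 2 lists were called. Of male-biased genes 12 of 15 rose and 0 fell (12 and 0 adjusted over the list alone), and 4 rose and 1 fell with the sex pattern as a covariate. The steroid dehydrogenase Hsd3b5 (4.49 ± 0.77) was among them, and the urinary protein gene Mup21, outside the list, rose by 3.29 ± 0.42. The male-biased median was 2.31 (2.39 with the slide as a block, 2.26 on slide 1, 2.15 on slide 2), with camera adjusted p = 3.79e-10 and adjusted p = 0.0282 with an estimated correlation. With members undetected in a group held at their bound it was 1.95, the largest such shift of any list. Of female-biased genes 8 of 12 fell and 0 rose (10 and 0 adjusted over the list alone), and 0 rose and 5 fell with the sex pattern as a covariate. The female-biased median was -1.85 (-1.87 with the slide as a block, -1.83 on slide 1, -1.88 on slide 2), with camera adjusted p = 4.05e-09 and adjusted p = 0.0282 with an estimated correlation. Cyp4a12a, a male-biased fatty acid hydroxylase, rose by 7.68 ± 0.53. It also rose in wild type (8.28 ± 0.53), where the 2 IL-13 arrays with Xist gave 8.18.

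Of the genes given above as changed in Alb-Cre, Acot1, Cyp4a31, Tk1, Slc4a1, Hsd3b5 and Mup21 did not pass with the sex pattern as a covariate. Other named genes did not pass with it either, such as Timp1, Mfsd2a and Rgs16 (limma adjusted p = 0.0822, 0.0617 and 0.347). The 3 IL-13 arrays lay on 1 side of the 4 EGFP arrays for 1719 of the 1840 genes, for 84 of the 90 named genes that changed, and for 28.9% of all genes, where chance gives 5.71%. The count was 1891 with the slide as a block and 851 on slide 1. The 90 named genes kept their sign on both slides, which for the 84 without overlap is fixed in advance. Of the called genes 58.7% were higher, against 78.7% with the authors' scaled values, 68.7% on slide 1 and 74.0% on slide 2.

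The 2 comparisons share no array, and their calls overlapped. Both genotypes raised 798 genes, where independent lists would share 232, and lowered 532, where they would share 146. Another 55 genes changed in opposite directions. The log2 changes correlated across genes with r = 0.687, and genes are not independent replicates.

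**Figure D3:**
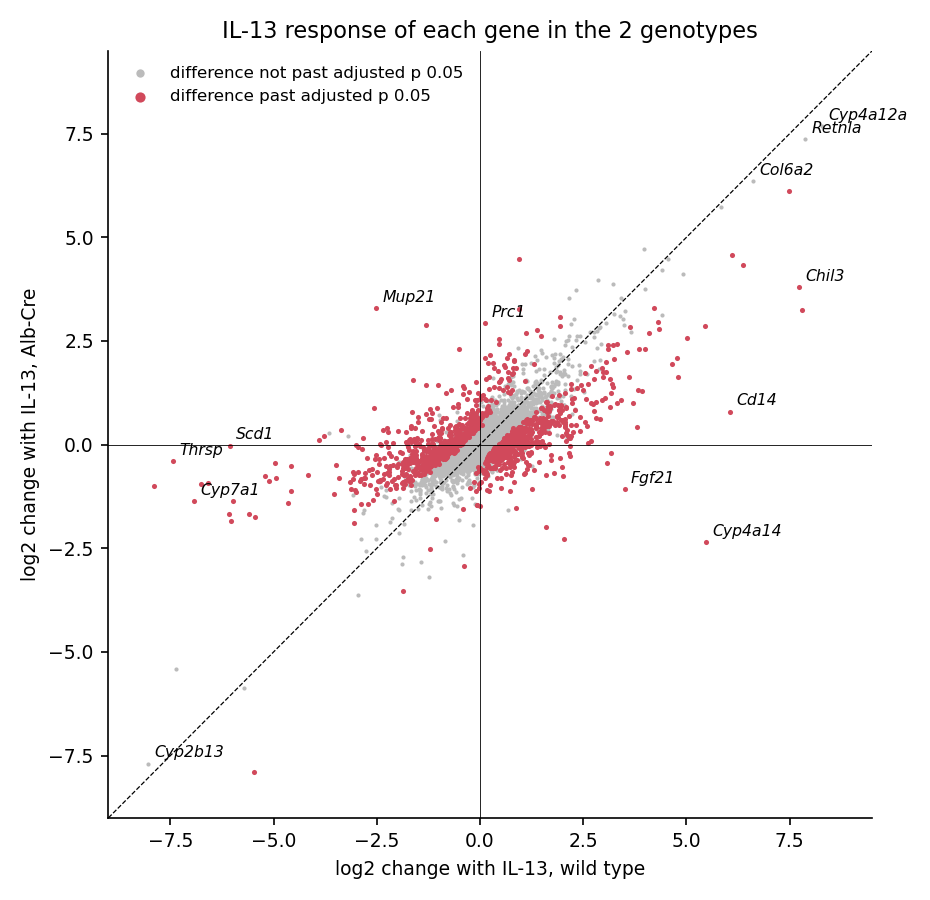
Log2 change with IL-13 in Alb-Cre (vertical) against wild type (horizontal) for each of the 9711 genes, with the line of equal change. Red points are the 1277 genes whose difference passed an adjusted p of 0.05, and Thrsp and Scd1 lie far from the line, near no change in Alb-Cre.

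The difference of the responses asks which IL-13 effects depend on the genotype. Relative to wild type, the Alb-Cre response was higher for lipid and sterol synthesis, drug metabolism, interferon stimulated and cell cycle genes, and lower for fatty acid oxidation, lipid droplet and type 2 immune genes. The sterol list's set test did not pass with an estimated correlation. It was higher by 7.03 ± 0.42 for Thrsp (adjusted p = 1.43e-07), by 6.05 ± 0.78 for Scd1 (adjusted p = 1.22e-04) and by 5.55 ± 0.65 for Cyp7a1 (adjusted p = 5.48e-05). It was lower for Cyp4a14 (-7.83 ± 0.97, adjusted p = 8.21e-05), Cd14 (-5.27 ± 0.36, adjusted p = 5.53e-07) and Fgf21 (-4.57 ± 0.48, adjusted p = 1.73e-05). Of 9711 genes 1277 differed, 646 with the higher and 631 with the lower value in Alb-Cre. The IL-13 arrays differed in sex pattern (Eif2s3y on 1 of 3 in wild type and 3 of 3 in Alb-Cre). With only the 4 IL-13 arrays that had Eif2s3y, 968 genes passed, the lone wild-type array being assumed to vary like the other groups.

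Of cholesterol synthesis genes 16 of 18 were higher in Alb-Cre and 0 lower (17 and 0 adjusted over the list alone), and 14 were higher and 0 lower with IL-13 arrays of 1 sex pattern. They included Dhcr7 (2.99 ± 0.40) and Sqle (2.74 ± 0.85). With the sex pattern as a covariate 9 were higher and 0 lower, and Sqle did not pass (1.99, adjusted p = 0.268). The cholesterol median was 2.08 (2.08 with the slide as a block, 2.17 on slide 1, 1.86 on slide 2), with camera adjusted p = 1.07e-13 and adjusted p = 0.135 with an estimated correlation. Of fatty acid synthesis genes 13 of 22 were higher and 0 lower (14 and 0 adjusted over the list alone), and 10 were higher and 0 lower with IL-13 arrays of 1 sex pattern. They included Elovl6 (4.01 ± 0.47) and Srebf1 (3.00 ± 0.28). The fatty acid synthesis median was 1.10 (1.10 with the slide as a block, 0.98 on slide 1, 1.57 on slide 2), with camera adjusted p = 7.75e-12 and adjusted p = 0.0378 with an estimated correlation. Of bile acid synthesis genes 7 of 15 were higher and 1 lower (7 and 2 adjusted over the list alone), and 4 were higher and 1 lower with IL-13 arrays of 1 sex pattern. Cyp8b1 differed by 5.83 ± 0.61. The bile acid synthesis median was 0.31 (0.31 with the slide as a block, 0.20 on slide 1, 0.39 on slide 2), with camera adjusted p = 0.00318 and adjusted p = 0.135 with an estimated correlation. Of drug metabolism genes 14 of 39 were higher and 2 lower (16 and 2 adjusted over the list alone), and 13 were higher and 1 lower with IL-13 arrays of 1 sex pattern. They included Cyp3a11 (5.67 ± 0.54) and Cyp1a2 (4.63 ± 0.28). The drug metabolism median was 0.55 (0.55 with the slide as a block, 0.37 on slide 1, 0.87 on slide 2), with camera adjusted p = 2.50e-06 and adjusted p = 0.0471 with an estimated correlation. Of hepatocyte markers 5 of 25 were higher and 0 lower (7 and 0 adjusted over the list alone), and 3 were higher and 0 lower with IL-13 arrays of 1 sex pattern. The hepatocyte median was 0.23 (0.23 with the slide as a block, 0.30 on slide 1, 0.12 on slide 2), with camera adjusted p = 0.0361 and adjusted p = 0.248 with an estimated correlation.

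Of fatty acid oxidation and PPAR alpha genes 17 of 30 were lower and 0 higher (22 and 0 adjusted over the list alone), and 0 were higher and 14 lower with IL-13 arrays of 1 sex pattern. They included Pdk4 (-3.52 ± 0.50) and Acot1 (-3.59 ± 0.40). The oxidation median was -0.96 (-0.96 with the slide as a block, -1.07 on slide 1, -0.71 on slide 2), with camera adjusted p = 2.10e-14 and adjusted p = 0.0378 with an estimated correlation. Of lipid droplet genes 7 of 19 were lower and 0 higher (9 and 1 adjusted over the list alone), and 0 were higher and 5 lower with IL-13 arrays of 1 sex pattern. They included Apoa4 (-3.35 ± 0.25) and Plin2 (-2.31 ± 0.34). The lipid droplet median was -0.54 (-0.54 with the slide as a block, -0.75 on slide 1, -0.37 on slide 2), with camera adjusted p = 3.82e-05 and adjusted p = 0.0442 with an estimated correlation. Of type 2 genes 9 of 19 were lower and 1 higher (11 and 1 adjusted over the list alone), and 0 were higher and 8 lower with IL-13 arrays of 1 sex pattern. Ccl11 (-2.57 ± 0.29) and Mgl2 (-1.94 ± 0.16) differed, and Ccl24 did not (-0.34 ± 0.36, adjusted p = 0.607). The type 2 median was -0.51 (-0.51 with the slide as a block, -0.45 on slide 1, -0.85 on slide 2), with camera adjusted p = 2.34e-07 and adjusted p = 0.0378 with an estimated correlation. Of injury genes 7 of 17 were lower and 0 higher (7 and 0 adjusted over the list alone), and 0 were higher and 5 lower with IL-13 arrays of 1 sex pattern. The injury median was -0.17 (-0.17 with the slide as a block, -0.42 on slide 1, -0.23 on slide 2), with camera adjusted p = 0.0154 and adjusted p = 0.0874 with an estimated correlation. Of unfolded protein response genes 6 of 21 were lower and 0 higher (7 and 1 adjusted over the list alone), and 0 were higher and 5 lower with IL-13 arrays of 1 sex pattern, with the pseudokinase Trib3 at -1.85 ± 0.21. The unfolded protein response median was -0.21 (-0.21 with the slide as a block, -0.22 on slide 1, -0.57 on slide 2), with camera adjusted p = 0.0112 and adjusted p = 0.268 with an estimated correlation.

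Of interferon stimulated genes 14 of 28 were higher and 0 lower (18 and 0 adjusted over the list alone), and 8 were higher and 1 lower with IL-13 arrays of 1 sex pattern. They included Oas2 (1.80 ± 0.21) and Oasl2 (1.47 ± 0.19). The interferon median was 0.69 (0.69 with the slide as a block, 0.74 on slide 1, 0.81 on slide 2), with camera adjusted p = 4.90e-08 and adjusted p = 0.0442 with an estimated correlation. Of cell cycle genes 16 of 29 were higher and 1 lower (18 and 1 adjusted over the list alone), and 10 were higher and 0 lower with IL-13 arrays of 1 sex pattern. They included Prc1 (2.81 ± 0.36) and Tk1 (2.35 ± 0.37), which fell in both genotypes. The cell cycle median was 0.68 (0.68 with the slide as a block, 0.73 on slide 1, 0.83 on slide 2), with camera adjusted p = 3.72e-11 and adjusted p = 0.0378 with an estimated correlation. Of antigen presentation genes 6 of 12 were higher and 0 lower (7 and 0 adjusted over the list alone), and 4 were higher and 0 lower with IL-13 arrays of 1 sex pattern. They included Cd74 (1.08 ± 0.20) and H2-Ab1 (1.26 ± 0.22). The antigen presentation median was 0.55 (0.55 with the slide as a block, 0.56 on slide 1, 0.73 on slide 2), with camera adjusted p = 2.65e-04 and adjusted p = 0.159 with an estimated correlation. Of male-biased genes 4 of 15 were higher and 1 lower (8 and 1 adjusted over the list alone), and 1 were higher and 0 lower with IL-13 arrays of 1 sex pattern. The male-biased median was 1.20 (1.20 with the slide as a block, 0.78 on slide 1, 0.92 on slide 2), with camera adjusted p = 2.80e-04 and adjusted p = 0.159 with an estimated correlation.

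Matrix genes went both ways, as 5 of 32 were higher and 4 lower (9 and 5 adjusted over the list alone), and 7 were higher and 3 lower with IL-13 arrays of 1 sex pattern. Col6a2 (-0.26 ± 0.23, adjusted p = 0.528) and Col1a1 (0.73 ± 0.38, adjusted p = 0.236) did not pass, whereas Col14a1 (1.78 ± 0.29) and Timp1 (-1.07 ± 0.21) differed. The matrix median was 0.37 (0.37 with the slide as a block, 0.27 on slide 1, 0.44 on slide 2), with camera adjusted p = 0.0533. By limma 0 of 11 neutrophil markers were higher and 0 lower, with 3 at an unadjusted p under 0.05 and 0 adjusted over the list alone. The neutrophil median was -0.21 (-0.21 with the slide as a block, -0.24 on slide 1, -0.010 on slide 2), with camera adjusted p = 0.618. With IL-13 arrays of 1 sex pattern the median was 0.47, with 1 marker higher and 0 lower.

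**Figure D4:**
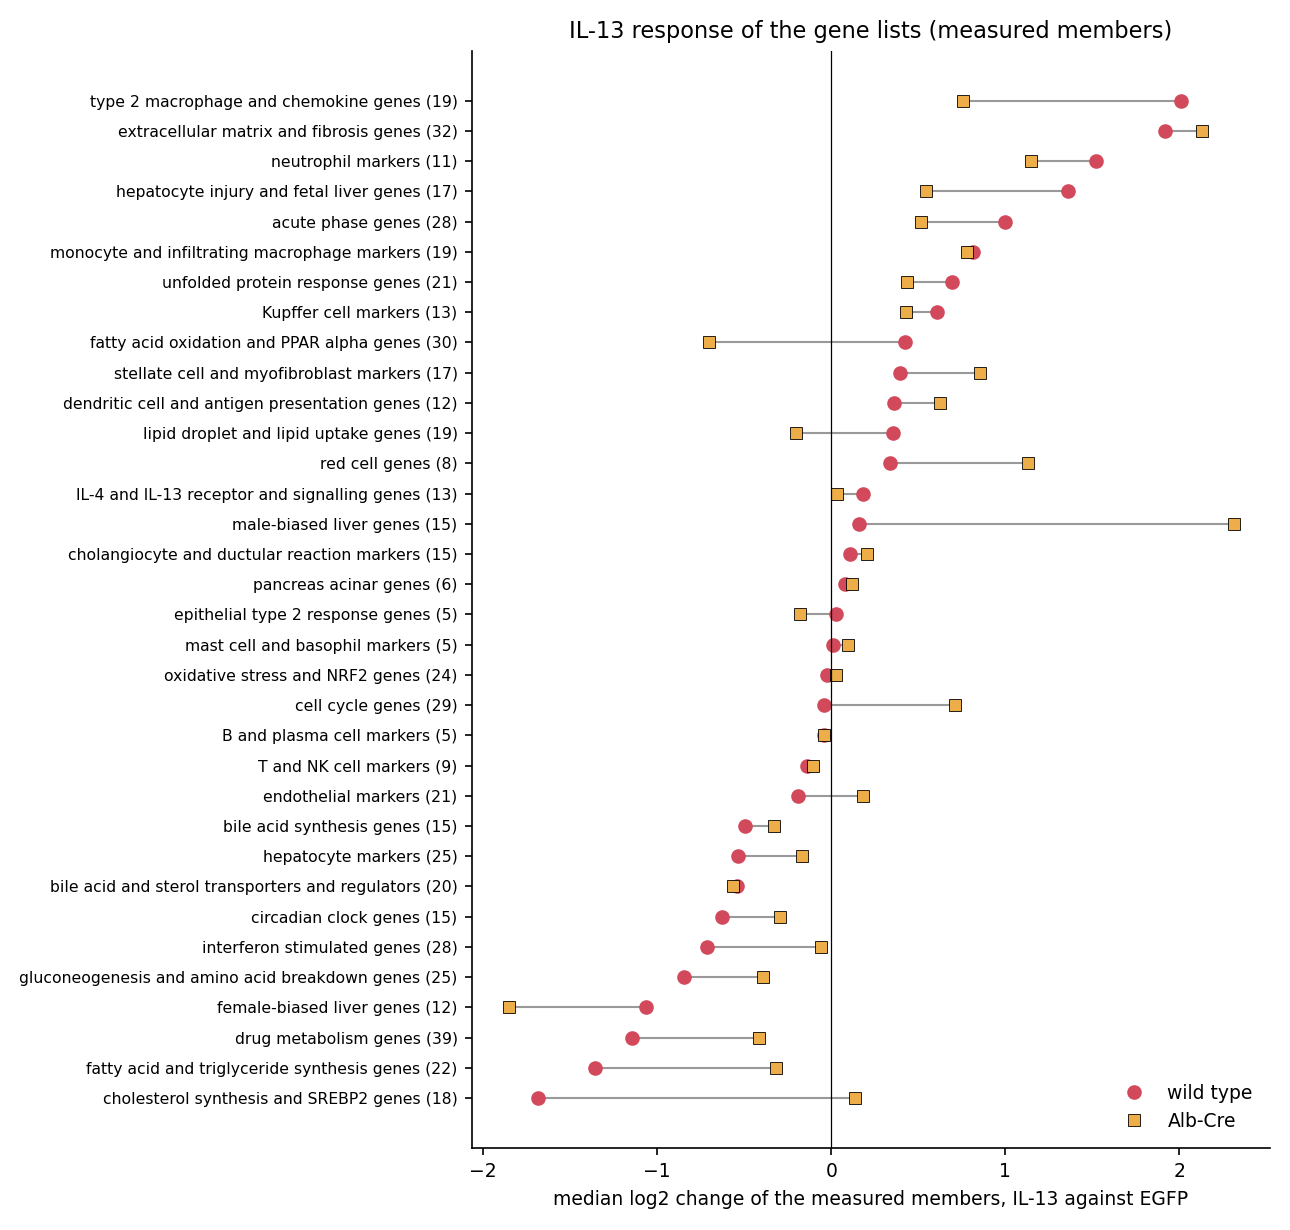
Median log2 change with IL-13 of the measured members of each list given a set test, in wild type (circles) and Alb-Cre (squares), with the number measured in brackets. Matrix genes lie at 1.92 and 2.13, and cholesterol synthesis genes at -1.69 and 0.14.

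The number of differing genes was 1345 with the slide as a block and 226 on slide 1. The 79 named genes that differed kept their sign on both slides. They were chosen from these same arrays, so this is no separate support. With the authors' scaled values 69.8% of the differing genes were higher in Alb-Cre, against 50.6%.

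Compared directly under IL-13, Alb-Cre livers had more Thrsp (6.58 ± 0.32, adjusted p = 3.91e-09), Cyp8b1 (5.77 ± 0.46, adjusted p = 4.30e-07) and Mup21 (6.35 ± 0.45, adjusted p = 1.25e-07), and at least 114-fold more Car3 (adjusted p = 2.09e-08). They had less Cyp4a14 (-6.29 ± 0.73, adjusted p = 2.20e-05), Cd14 (-5.49 ± 0.27, adjusted p = 5.07e-09) and Ly6d (-4.55 ± 0.73, adjusted p = 3.73e-04). Retnla did not pass (-0.49 ± 0.18, adjusted p = 0.0618). Of 9711 genes 2130 differed, 1039 higher and 1091 lower in Alb-Cre. The count was 2222 with the slide as a block, 922 on slide 1 and 937 on slide 2, which compares 1 array with 1. It was 1329 with the 4 IL-13 arrays that had Eif2s3y and 1235 with only the 6 arrays compared in the fit.

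With EGFP, no gene passed the threshold between the genotypes, which does not show that they are equal. limma called 0 of 9711 genes (smallest adjusted p = 0.839), and 364 had an unadjusted p under 0.05. The count was 0 with the slide as a block, 0 on slide 1 and 1 on slide 2. Alb, whose promoter drives the Cre, measured 10.08 ± 0.37 in wild type and 9.87 ± 0.19 in Alb-Cre (SD, n = 4 each). Camera at the preset correlation placed cholesterol synthesis and cell cycle genes lower in Alb-Cre and unfolded protein response genes higher, and none of the 3 passed with an estimated correlation. limma called 0 members of these lists (1, 4 and 2 had an unadjusted p under 0.05). The cholesterol median was -0.25 (-0.25 with the slide as a block, -0.27 on slide 1, -0.32 on slide 2), with camera adjusted p = 0.00129 and adjusted p = 0.726 with an estimated correlation. The cell cycle median was -0.13 (-0.13 with the slide as a block, 0.021 on slide 1, -0.19 on slide 2), with camera adjusted p = 0.0368 and adjusted p = 0.623 with an estimated correlation. The unfolded protein response median was 0.13 (0.13 with the slide as a block, 0.20 on slide 1, 0.13 on slide 2), with camera adjusted p = 0.00129 and adjusted p = 0.623 with an estimated correlation.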

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

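The tests on sex differences, on a proportional response and on hepatocyte share were chosen after the results were seen, and the splits of the arrays before.

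The number of genes whose IL-13 response differed between genotypes, 1277, drew a closer look, as did 79 named genes with such a difference. Of 100 splits of the arrays 1 gave as many genes (real 1277, highest other 1256). The 6 other splits that kept the IL-13 arrays' genotypes and regrouped the EGFP arrays alone gave 1008 to 1256 genes, and the 93 that regrouped the IL-13 arrays gave at most 2, so the count follows the parting of the 6 IL-13 arrays, whose 10 splits are too few for a share under 0.05. A sex difference between the IL-13 animals might account for it, since 1 of 3 wild-type and 3 of 3 Alb-Cre IL-13 arrays had Eif2s3y. With only those 4 IL-13 arrays 968 genes passed, all 1277 kept their sign and 707 of them passed, which argues against it as the whole cause, although 1 wild-type array carries that comparison. A weaker effect of 1 proportion on all responsive genes is argued against by slopes of the Alb-Cre on the wild-type change of 1.01 over matrix genes (0.980 to 1.04 with each array left out) and 0.0707 over fatty acid synthesis genes (0.00180 to 0.132). A sex difference stays open, as does an effect of the Alb-Cre genotype on hepatocyte genes, the one the design names. The latter was not tested further, because Il4ra is not analysed here.

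The values for Chil3, Rnase2a, Ch25h, Cidec, Cyp2b9, Top2a, Asns, Ly6d, Susd4, Car3, Car4 and Rab15, each undetected in at least 1 group, depend on the offset. The named differences (Alb-Cre minus wild-type response, log2) were as follows for immune and acute phase genes: -2.57 for Ccl11, -3.92 for Chil3, -1.36 for Rnase2a, -2.15 for Ch25h, -1.94 for Mgl2, -2.50 for Ccl6, -0.78 for Lgals3, -1.78 for Cd163, 2.15 for Clec4f, -5.27 for Cd14, -1.47 for Lbp, -0.72 for Serpina3n, 1.08 for Cd74 and 1.26 for H2-Ab1. Interferon stimulated and cell cycle genes gave 1.48 for Gbp3, 1.94 for Ifit3, 1.47 for Oasl2, 1.80 for Oas2, 2.35 for Tk1, 2.81 for Prc1, 1.39 for Top2a and 1.62 for Birc5. Matrix, stellate, ductular, endothelial and red cell genes gave -1.07 for Timp1, -1.54 for Lum, 1.78 for Col14a1, 1.85 for Mmp13, 2.89 for Reln, -2.25 for Cygb, -0.81 for Sox9, -1.54 for Vwf and 2.06 for Alas2. For synthesis and transport of bile acids and lipids the differences were 5.55 for Cyp7a1, 5.83 for Cyp8b1, 2.24 for Akr1c6, 1.86 for Abcb11, 2.13 for Hmgcs1, 2.74 for Sqle, 1.98 for Sc5d, 2.09 for Tm7sf2, 2.99 for Dhcr7, 6.05 for Scd1, 7.03 for Thrsp, 3.00 for Srebf1, 1.75 for Mlxipl and 4.01 for Elovl6. Lipid droplet and oxidation genes gave -2.31 for Plin2, -1.37 for Pparg, -3.39 for Cidec, -1.86 for Hilpda, -3.35 for Apoa4, -7.83 for Cyp4a14, -4.33 for Cyp4a31, -4.57 for Fgf21, -3.52 for Pdk4, -3.59 for Acot1 and -1.48 for Etfdh. Cytochromes and hepatocyte genes gave 4.63 for Cyp1a2, 5.67 for Cyp3a11, 4.07 for Cyp2c29, -2.42 for Cyp2b9, -1.66 for Cyp2c39, 1.31 for Alb, 0.81 for Hpd, 4.41 for Upp2 and 6.91 for Car3. The clock gene Dbp gave 1.56, and Rgs16, outside the lists, -2.56. Stress and injury genes gave -2.45 for the brightest of 3 Asns probes, -2.70 for Chac1, -1.85 for Trib3, -4.54 for Ly6d, -0.90 for Cd63 and -1.33 for Tnfrsf12a. Car4 and Rab15, outside the lists, gave -1.54 and -2.04. Sex-biased genes gave -0.83 for Susd4, 4.19 for Selenbp2, 3.55 for Hsd3b5 and 5.81 for Mup21. With IL-13 arrays of 1 sex pattern Sox9, Abcb11, Pparg, Cyp2b9, Alb, Hpd, Gbp3, Lgals3, Chac1, Cd63, Susd4, Hsd3b5 and Rgs16 did not pass, among them Cyp2b9 at -0.33, Hsd3b5 at 1.99, Pparg at -0.90, Rgs16 at -1.68 and Susd4 at -0.52, and Cyp2c39 passed at -0.999. With the pattern as a covariate Hmgcs1, Sqle, Alas2 and Dbp did not pass either. For genes with several probes these are values of the brightest probe, and other probes can show less. The second Cyp2c29 probe changed by -0.27 in wild type and -0.15 in Alb-Cre, and the second Mmp13 probe by 0.037 and 0.053. The second Oasl2 probe changed by -0.38 and 0.069, and the second Pparg probe by 0.19 and -0.012.

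Some sex-biased liver genes changed with IL-13 in both genotypes. In wild type the male-biased list did not pass by camera, and the female-biased list passed at the preset correlation but not with an estimated one. In wild type, of 14 called list genes apart from Xist and Y-linked genes, 11 passed in the same direction with only the 2 IL-13 arrays that had Xist like their controls. This argues against a sex difference between the animals as the cause for those 11 genes, and Cyp4a12a, at 8.18 on those arrays, may reflect an effect of IL-13 on sex-biased expression. In Alb-Cre, 8 of 17 called list genes passed with the pattern as a covariate, a term that rests on the wild-type arrays. There the sex difference and the plasmid cannot be told apart, because no Alb-Cre array separates them.

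The fall of hepatocyte metabolism genes with IL-13 in wild type could come from a lower share of hepatocytes. The median change of 94 bile acid, sterol, fatty acid and drug metabolism genes lay -0.83 from that of 25 hepatocyte markers, which goes against it. The 95% interval by resampling genes was -1.48 to -0.20. It is too narrow, because it takes genes as independent and leaves out the spread between arrays. Cholesterol synthesis genes had an estimated correlation of 0.69. Against the 13 dimmer markers the difference was -0.52 (-1.38 to 0.13), so compression of the brightest probes, which would hide a fall of the markers, stays open. At equal brightness the metabolism genes lay -1.45 ± 0.40 (SE) from the markers over 119 genes, but the change rose with brightness among markers (Spearman 0.435) and not among metabolism genes (-0.189), so this adjustment decides little. A lower share as the whole cause would raise the markers of all other cell types alike. The medians of 1.52 for neutrophil and -0.19 for endothelial markers, 1.71 apart, go against that. Their interval (0.37 to 2.15) is too narrow for the same reason. A smaller part of the fall and an influx of neutrophils stay open.

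Only the real split of the arrays gave as many genes changed by IL-13 in wild type (1 of 35 splits, real 3952, highest other 1288). The same held in Alb-Cre (1 of 35, real 1840, highest other 415). A share of 1 in 35 is under 0.05 but the smallest these splits can give. In Alb-Cre the real split is also the split by sex pattern, so it does not tell the plasmid from that pattern. For the genes called in both (1 of 100, real 1330, highest other 2) the splits do not test the sharing. Reassigning the plasmid weakens the response of each genotype before the calls are compared. Chance was not excluded for the number of gene lists, which was 21 in wild type (2 of 35, highest other 21), 21 in Alb-Cre (2 of 35, highest other 21) and 14 in the difference (8 of 100, highest other 16). For the 0 genes between genotypes with EGFP the splits decide nothing, since every split gives at least as many (35 of 35, highest other 1). Between genotypes under IL-13 the 10 splits are too few for a share under 0.05 (value 1, real 2130, highest other 3).

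A single EGFP array stood apart from the other 3 of its group in 14 of 254 groups of values tested, where chance gives 12.7. The gap as a share of the range is given in brackets. Arrays lying highest were Chil3 in wild-type EGFP replicate 1 (0.830), Chil3 in Alb-Cre EGFP replicate 2 (0.901), Krt23 in Alb-Cre EGFP replicate 4 (0.830), Fasn in Alb-Cre EGFP replicate 2 (0.889), Mlxipl in Alb-Cre EGFP replicate 1 (0.891), Hpd in wild-type EGFP replicate 2 (1.00), Rgs16 in wild-type EGFP replicate 4 (0.886) and Etfdh in Alb-Cre EGFP replicate 1 (0.872). Arrays lying lowest were Ccl11 in Alb-Cre EGFP replicate 1 (0.912), Cygb in wild-type EGFP replicate 3 (0.832), Cyp2c29 in Alb-Cre EGFP replicate 1 (0.857), Cyp2b13 in wild-type EGFP replicate 2 (0.883) and Vwf in wild-type EGFP replicate 2 (0.901), and wild-type EGFP replicate 3 had the fewest probes detected of its group (0.836).

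Of 835 kept probes without a gene symbol, outside the gene counts, 340 changed with IL-13 in wild type (166 up, 174 down), 151 in Alb-Cre (73 up, 78 down), and 106 differed between the responses (56 higher, 50 lower in Alb-Cre).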

How the results depend on the processing

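The covariate for the Eif2s3y and Xist pattern, the fit with IL-13 arrays of 1 pattern and the fit without sex-biased lists were chosen after seeing the data. Under the other normalizations, offset, filters, array weights and empirical Bayes settings, and with each array left out, gene counts stayed within 1.5 times those above: 3431 to 3981 genes in wild type, 1332 to 2069 in Alb-Cre, 869 to 1349 for the difference, 1476 to 2095 between genotypes under IL-13, 0 to 0 with EGFP, and 976 to 1382 in both genotypes. These ranges leave out the fit that counts probes. In that fit 50.5% of the called probes were higher in wild type and 54.0% in Alb-Cre. Lists past the threshold ranged over 20 to 21, 20 to 23 and 13 to 18. Il13 ranged over -0.21 to -0.051 in wild type and -0.35 to -0.099 in Alb-Cre and never passed. Counts were lower with 1 slide, a stricter threshold or fewer arrays than with all. In wild type slide 2 alone gave 2449 and a fold of at least 1.5 gave 2326. In Alb-Cre slides 1 and 2 gave 851 and 620, a fold of at least 1.5 gave 1076 and an adjusted p under 0.01 gave 1038. For the difference these were 226, 597 and, under 0.01, 548. Under IL-13 they were 922 and 937, 1222 with the fold and 1189 under 0.01, 1235 with only the 6 arrays compared, and 1329 with IL-13 arrays of 1 pattern. Slide 2 alone gave 1 gene with EGFP. An estimated correlation left 5, 12 and 7 lists of 21, 21 and 14. No scaling moved the median of all genes by over 0.1.

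The covariate left 815 genes in Alb-Cre, 1257 between genotypes under IL-13, 653 in both genotypes and 890 for the difference. Under it the Alb-Cre change no longer passed, with the other sign, for Fgf21 (0.0021, adjusted p = 0.999), Cd14 (-0.46, adjusted p = 0.410) and Eif2s3y (-0.37, adjusted p = 0.221), and it reversed for Reg1 (-2.38). The set test, too, no longer passed and had the other direction for the acute phase (median 0.13) and unfolded protein response lists (0.077). For Eif2s3y this follows from the covariate's construction, and Reg1 was high on the wild-type IL-13 array with Eif2s3y, from which the term is estimated. For the others the cause was not tested. Scd1 in Alb-Cre, -0.021 and not called (-0.67 to 1.07 with each array left out), passed at 1.01 on slide 2, where it rests on 1 IL-13 array, and at 1.07 without Alb-Cre IL-13 replicate 2. Over all named genes and lists 12143 values kept their side of the threshold, counting changes of sign with no call in either fit. Another 477 lost and 151 gained a call. The 8 that changed direction with a call in at least 1 of the 2 fits are those given above.

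Samples with the same replicate number in their titles did not deviate together (median r 0.0188 over 19 pairs, -0.121 to 0.283), so the numbers do not pair them. With the replicate number as a block 3830 genes changed in wild type and 1633 in Alb-Cre, 1240 differed in response, 2098 under IL-13 and 0 with EGFP. The blocked lists numbered 21, 21 and 14, and Il13 changed by -0.15 and -0.26. The alternatives for Il4ra were not run, because no probe carried its name.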

Other observations

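The fit with the sex pattern as a covariate was chosen after the results were seen, and the lists and other tests before.

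Endothelial markers went both ways. In wild type 7 of 21 rose and 6 fell (8 up and 7 down when adjusted over the list alone, median log2 change -0.19, camera adjusted p = 0.986, adjusted p = 0.986 with an estimated correlation), and the median and the mean (0.099) differed in sign. The von Willebrand factor gene Vwf rose (3.85 ± 0.19, adjusted p = 3.04e-10), as did Pecam1 (1.32 ± 0.15, adjusted p = 2.80e-06), and the sinusoidal lectin Clec4g fell (-2.51 ± 0.31, adjusted p = 1.08e-05). In Alb-Cre 7 rose and 3 fell (7 up and 3 down when adjusted over the list alone, median log2 change 0.18, camera adjusted p = 0.0718, adjusted p = 0.381 with an estimated correlation, fry upward at adjusted p = 0.00304), with Vwf at 2.30 ± 0.19, Pecam1 at 1.46 ± 0.15 and Clec4g at -1.93 ± 0.31 (3 rose and 2 fell with the sex pattern as a covariate), and the Vwf response was smaller in Alb-Cre (-1.54 ± 0.27, adjusted p = 0.00130). The list's median was -0.19 with the slide as a block, -0.30 on slide 1 and 0.062 on slide 2 in wild type. Of the 2 eosinophil markers measured, 0 rose in wild type and 2 in Alb-Cre (median 0.32, 0.046 with both held at their bound), where Prg2 (adjusted p = 0.0207) and Ccr3 (adjusted p = 0.0196) were undetected with EGFP and close to the floor with IL-13. With the sex pattern as a covariate neither passed (adjusted p = 0.156 and 0.267). The histamine-forming enzyme Hdc, on the mast cell list, rose in wild type (1.32 ± 0.15, adjusted p = 4.06e-06) and Alb-Cre (1.06 ± 0.15, adjusted p = 1.01e-04).

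Clock and amino acid genes fell in wild type. Of 15 clock genes 9 fell and 1 rose (1 up and 9 down when adjusted over the list alone, median log2 change -0.63, camera adjusted p = 0.0150, adjusted p = 0.147 with an estimated correlation), among them the clock output gene Dbp (-2.21 ± 0.31, adjusted p = 3.07e-05), whose response differed in Alb-Cre (1.56 ± 0.44, adjusted p = 0.0274), and Ciart (-2.41 ± 0.32, adjusted p = 1.68e-05). Gluconeogenesis and amino acid breakdown genes fell in 14 of 25 cases and rose in 1 (1 up and 15 down when adjusted over the list alone, median log2 change -0.85, camera adjusted p = 7.23e-04, adjusted p = 0.352 with an estimated correlation), including the tyrosine-degrading enzyme Hpd (-1.86 ± 0.16, adjusted p = 1.71e-07). Their medians were -0.68 with the slide as a block, -0.61 on slide 1 and -0.80 on slide 2 for clock and -0.80 with the slide as a block, -0.88 on slide 1 and -0.47 on slide 2 for amino acid genes. In Alb-Cre the clock list had a median of -0.29 (camera adjusted p = 0.0619, adjusted p = 0.232 with an estimated correlation) and the amino acid list -0.40 (camera adjusted p = 6.59e-04, adjusted p = 0.362 with an estimated correlation). With the sex pattern as a covariate 0 clock and 5 amino acid genes fell there, and 0 and 0 rose.

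The remaining lists in wild type gave no call by camera. Fry called several, among them receptor and signalling genes (adjusted p = 7.6e-05), ductular markers (2.0e-04) and antigen presentation genes (0.0035) upward. It called T and NK cell markers (0.016) downward. Rising and falling members were 5 and 1 of 13 for receptor and signalling genes (median 0.18, camera adjusted p = 0.155), 0 and 2 of 5 for epithelial type 2 genes (0.028, mean -0.11, camera adjusted p = 0.631), 5 and 2 of 15 for ductular markers (0.11, camera adjusted p = 0.110) and 2 and 6 of 29 for cell cycle genes (-0.041, camera adjusted p = 0.457). They were 1 and 3 of 9 for T and NK cells (-0.14, camera adjusted p = 0.438), 1 and 1 of 5 for B and plasma cells (-0.042, mean 0.12, camera adjusted p = 0.986), 6 and 1 of 12 for antigen presentation (0.36, camera adjusted p = 0.110) and 1 and 0 of 5 for mast cells (0.012, camera adjusted p = 0.631). For red cells they were 2 and 0 of 8 (0.34, camera adjusted p = 0.483), for pancreas acinar genes 2 and 1 of 6 (0.079, camera adjusted p = 0.986), for oxidative stress genes 7 and 7 of 24 (-0.026, mean 0.0036, camera adjusted p = 0.986) and for male-biased genes 4 and 2 of 15 (0.16, camera adjusted p = 0.228). The male-biased median was 0.091 on slide 1, whose wild-type IL-13 arrays had Xist, and 0.95 on slide 2, whose single one had Eif2s3y. Where a mean is given, its sign differed from the median's. With members undetected in a group held at their bound the median was -0.045 for T and NK cells, 0.0043 for mast cells, -0.0078 for pancreas acinar, -0.012 for oxidative stress and 0 for male-biased genes. Adipocyte genes, without a set test, gave 0 and 1 of 4 (median -0.22). Female-biased genes did pass, with 8 of 12 down (0 up and 8 down when adjusted over the list alone, median log2 change -1.07, camera adjusted p = 3.80e-04, adjusted p = 0.147 with an estimated correlation).

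In Alb-Cre 6 lists not given above passed by camera at the preset correlation. The adjusted p with an estimated correlation is marked estimated, and members that rose and fell come first, and last with the sex pattern as a covariate. These were 5 and 1 of 15 for ductular markers (0.21, camera adjusted p = 0.0194, 0.209 estimated, 2 and 0 with the covariate), 1 and 8 of 20 for bile acid and sterol transporters (-0.57, camera adjusted p = 2.17e-04, 0.0282 estimated, 0 and 2 with the covariate) and 0 and 2 of 25 for hepatocyte markers (-0.17, camera adjusted p = 0.0125, 0.155 estimated, 0 and 6 with the covariate). They were also 6 and 0 of 13 for Kupffer cell markers (0.43, camera adjusted p = 3.15e-04, 0.149 estimated, 4 and 0 with the covariate), 6 and 0 of 21 for unfolded protein response genes (0.44, camera adjusted p = 0.00738, 0.209 estimated, 1 and 1 with the covariate) and 7 and 1 of 17 for injury genes (0.54, camera adjusted p = 7.22e-04, 0.0282 estimated, 3 and 1 with the covariate). Bile acid synthesis genes (-0.33, camera adjusted p = 0.162), interferon stimulated genes (-0.061, camera adjusted p = 0.162) and lipid droplet genes (-0.20, camera adjusted p = 0.243) did not pass. By limma 11 of 15, 7 of 28 and 10 of 19 of their members had an unadjusted p under 0.05, against 3009 of all 9711 genes. With the covariate 0 rose and 2 fell, 0 rose and 1 fell, and 2 rose and 0 fell.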
